A study of Mus musculus with 2 samples.

How the data were processed

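ATAC-seq libraries of newborn mouse hindbrain were used as the peak lists deposited by the authors. There were 2 biological replicates of 1 group, replicate 1 from 15 mice and replicate 2 from a pool of unstated size. Per the labels, the assembly was mm10 and libraries were fragmented by transposase. The aligner, the peak caller, the handling of the transposase offset and their versions are not given in the sources used here. Each replicate had a list of peaks shared by pseudoreplicates, a ranked list and a list past the threshold of the irreproducible discovery rate (IDR). Both replicates together had the same kinds of list, a replicated list and a conservative thresholded list. Lists over both replicates were made from pooled alignments, per the deposited file descriptions, so the replicates were compared through the lists of the single replicates and the ranked list that holds a value for each. Read depth is unknown, and the lists hold only regions past a threshold.

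The deposited lists give each peak a score (whole numbers up to 1000), and the thresholded lists hold scores of 540 or more. The signal value of each peak is as deposited by the authors, and the quantity behind it is not named in the sources used here, so it was used only to describe and rank peaks within a list. The ranked list that pairs the replicates gives a deposited −log10 p for each peak in each replicate, without naming the replicate. In the ranked lists over both replicates, 14 further columns for single replicates or pseudoreplicates were not used.

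Peaks that shared a start and end were counted as 1 distinct region with its strongest summit. Annotation was GENCODE release M21 and sequence was GRCm38, whose chromosome lengths no peak exceeded. A gene had an open promoter if a region overlapped 500 bp either side of any TSS of its protein-coding transcripts. Distal regions had a strongest summit over 1 kb from every such TSS and were counted within 50 kb of the most upstream TSS. The 22 gene lists (360 genes, of which 26 are in more than 1 list) were compared with 10000 random lists, matched on promoter CpG content and TSS number, or on gene density and CpG content. Two-sided permutation p values were adjusted by Benjamini-Hochberg over the lists, at 0.05. Hindbrain and forebrain factors were compared by 100000 permutations and Fisher's exact test, and Hox groups by Fisher's exact test. The 25 motif strings were searched within 100 bp of distal summits and in 5 matched windows for each, from windows outside all ranked peaks, and 95.4% of distal windows found matches. Genes and windows are not replicates.

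Overlap needed 1 bp, and chance levels came from 20 random placements. Named genes followed a rule: Hox genes, and for each list up to 4 members with the strongest promoter over both replicates, up to 4 with the most distal regions and up to 4 with no region in either replicate. Outside the lists the rule took the 10 genes with most distal regions, the 10 strongest distal regions and 5 promoters in each direction of difference between the replicates. The promoters of the last kind are not reported, since percentiles within lists of different lengths are not comparable. Lists, motifs, the tests of the comparisons and the alternatives were chosen before the data were examined, and the tests of technical explanations after the comparisons were made. The alternatives were other promoter and gene windows, other peak lists, regions above the median signal, no matching, shuffled windows and each replicate alone.

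Statistics were tested on simulated data. Of 100 random lists without effect, drawn from 21829 genes, 1% reached p under 0.05 in promoter tests and 2% in distal tests. Their genes were drawn independently, so lists of neighbouring genes that share regions were not simulated. Lists with planted effects reached p under 0.05 in 100% of each kind of test. These effects were large, with every promoter set open or distal regions added to every gene, so power for smaller effects was not tested. A CTCF site planted in 10% of 5000 windows was found in 10.0%, with 1 motif called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0 were used.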

Results

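Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA, in hindbrain of newborn mice (age 0 days, both sexes pooled). The hindbrain holds the cerebellum, pons and medulla. Tissue pools formed 1 group with 2 biological replicates, of which replicate 1 came from 15 mice and replicate 2 from a pool of unstated size. The measurements are lists of accessible regions on mouse genome build mm10, made for each replicate and for both together. Read depth is unknown, so no precision that depends on it is given. With 1 library on each side, differences between the replicates have no test, and tests over genes or sequence windows describe these libraries and not a population of animals.

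Replicate 2 held more accessible regions than replicate 1. The reproducibility-thresholded list of replicate 1 held 20221 distinct regions covering 18.5 Mb, with a median width of 888 bp. That of replicate 2 held 26065 regions covering 23.8 Mb, with a median width of 878 bp. The larger number of thresholded peaks was 1.26 times the smaller. The conservative list over both replicates, used below unless another is named, held 31814 regions covering 29.5 Mb, or 1.08% of the chromosomes. Of the regions of replicate 1, 91.1% overlapped a region of replicate 2 by at least 1 bp (Wilson 95% interval 90.7% to 91.5%), against 1.83% for regions placed at random. Of the regions of replicate 2, 70.6% overlapped a region of replicate 1 (70.1% to 71.2%), against 1.44% at random. Intervals cover counting error only. Across all 151171 peaks in the ranked list that pairs the replicates, the −log10 p values of the replicates had a Spearman correlation of 0.707 and, on log values, a Pearson correlation of 0.805. Across the 77374 peaks past a threshold that selects for likeness between the replicates, the values were 0.750 and 0.773. The same replicate, which the list does not name, had the higher −log10 p in 70.3% of all peaks and 79.3% of those past the threshold. Its median ratio to the other was 1.39 and 1.53. These correlations are across peaks, which are not independent replicates.

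Promoters formed a large share of the accessible regions. The strongest summit lay within 1 kb of the transcription start site (TSS) of a protein-coding gene in 53.8% of the regions of replicate 1, 46.8% of those of replicate 2 and 39.6% of the conservative list, against 2.53% of random positions. Introns held 25.1% of the conservative regions, other exons 3.43% and intergenic sequence 31.8%. Random positions gave 34.5%, 3.15% and 59.8%. Promoter regions had a median signal value of 9.76 and distal regions of 5.63. The promoter share was 20.7% in the less strict replicated list.

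Of 21829 protein-coding genes, 58.4% had a region at a promoter (within 500 bp of any TSS), and the share rose with promoter CpG content, from 6.69% in the lowest of 5 equal groups to 96.3% in the highest. Gene lists were therefore compared with random lists of matched CpG content and TSS number. All 20 genes of synapse and axon had a promoter region, against 66.4% in matched lists (permutation adjusted p = 0.00126). Among regions above the median signal value this call was lost (permutation adjusted p = 0.657). The signal value given for a gene is that of the strongest region at any of its TSS. Nrxn1, a presynaptic adhesion molecule with its most upstream TSS at chromosome 17, 91093071, had signal values of 20.1 in replicate 1 and 18.9 in replicate 2. Syt1, a calcium sensor of synaptic vesicles, had 13.1 and 14.7. The granule cell lineage, which builds the largest neuron population of the cerebellum, had 18 of 20 promoters open, against 69.8% (permutation adjusted p = 0.0147). Among them, Etv1 had signal values of 11 and 11.7, and Cbln1, a secreted synapse organiser, 9.48 and 12.4. In the list of each replicate alone 15 of the 20 were open, and the call was lost (permutation adjusted p = 0.247 in replicate 1 and 0.609 in replicate 2). It was also lost with the most upstream TSS (0.0510) and above the median signal value (0.733), by the same permutation test. All 20 genes of ribosome and core metabolism were open, against 88.3% (permutation adjusted p = 0.193). This is the highest share possible, and the raw permutation p was still 0.132. The test could therefore not have called this list higher than matched lists.

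Promoters of regional transcription factors and of several neuron classes were open less often than matched promoters. Hindbrain and isthmus factors had 18 of 33 promoters open against 81.8%, midbrain factors 5 of 15 against 86.3% and forebrain factors 8 of 30 against 79.2%. Markers of cranial motor neurons (3 of 14, against 81.0%) and of GABA and glycine neurons (5 of 15, against 81.8%) were also lower, as was the endothelium (3 of 15, against 61.1%). The permutation adjusted p was 0.000733 for each of these 6 lists, from a raw p of 0.0002, the smallest that 10000 lists can give. Serotonin and noradrenaline neurons had 3 of 16 open against 57.4% (permutation adjusted p = 0.00275). The Purkinje cell lineage had 12 of 19 open against 83.2%, and skeletal and cardiac muscle 1 of 17 against 29.1% (permutation adjusted p = 0.0496 for both). The Purkinje call did not hold in replicate 1 (11 of 19, permutation adjusted p = 0.109) or replicate 2 (14 of 19, 0.501), and without matching its difference was 4.84 percentage points in the other direction. Without matching, the calls for hindbrain factors (permutation adjusted p = 0.855), midbrain factors and GABA and glycine neurons (0.129 for both) were lost. In the optimal list over both replicates, the calls for hindbrain factors (permutation adjusted p = 0.0875), Purkinje cells and GABA and glycine neurons (0.222) were lost. The muscle call was lost with the most upstream TSS (permutation adjusted p = 0.410), with 1000 bp either side of the TSS (0.173) and above the median signal value (0.0561). In the less strict replicated list 1 list was lower than matched lists, that of forebrain factors. There, 31 of 33 hindbrain and 21 of 30 forebrain factors had an open promoter.

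Single members differed widely. Pax5, a factor of the midbrain and hindbrain boundary, has its most upstream TSS at chromosome 4, 44710487. Its strongest region at any TSS had signal values of 10.6 in replicate 1 and 12.7 in replicate 2. Pbx3, a cofactor of Hox proteins, had 8.66 and 11.2. Among midbrain factors Pitx2 had 9.84 and 8.86, and among forebrain factors Satb2 had 5.57 and 5.35 and Lhx2 5.26 and 5.44. Itpr1, a calcium release channel abundant in Purkinje cells, had 19.3 and 17.7. Tbx3 had 10.9 and 13.5 and Nkx6-1 9.32 and 10.2 among cranial motor neuron markers, while Chat, Isl1 and Mnx1 had no promoter region in the list of either replicate (Isl1 was open in the conservative list). Tph2, which makes serotonin in neurons, had 6.83 and 7.56, and Dbh, which makes noradrenaline, had no promoter region. Of the GABA and glycine neuron genes, Slc6a1, a GABA transporter, had 5.98 and 7.84, while Gad1, which makes GABA, had a promoter region of signal 3.49 in the conservative list and none in the list of either replicate.

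The 11 other lists did not pass this test in the conservative list. They were glutamate neurons (10 of 14 open, adjusted p = 0.704), neural progenitors (14 of 18, 0.704), the oligodendrocyte lineage (5 of 16, 0.0744), the astrocyte lineage (13 of 16, 0.271), microglia (2 of 15, 0.166), mural cells and meninges (7 of 17, 0.317), ependyma and choroid plexus (8 of 14, 0.614), erythroid and lymphoid cells (1 of 16, 0.121), hepatocytes (2 of 17, 0.249), keratinocytes and gut epithelium (2 of 15, 0.200), and ribosome and core metabolism, given above, all by permutation. In replicate 1 alone 6 of them were lower than matched lists: progenitors (permutation adjusted p = 0.0419), oligodendrocytes (0.00275), mural cells (0.00616), ependyma (0.0112), erythroid cells (0.0315) and hepatocytes (0.0365). Progenitors, oligodendrocytes and mural cells were also lower above the median signal value. Without matching, microglia, erythroid cells, hepatocytes and keratinocytes were lower and ribosome and core metabolism higher than random lists. Rfx3 and Rfx2, regulators of genes for cilia, had the strongest promoters of the ependyma list, with signal values of 14 and 13.1 in replicate 1 and 15.6 and 16.7 in replicate 2.

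**Figure D1:**
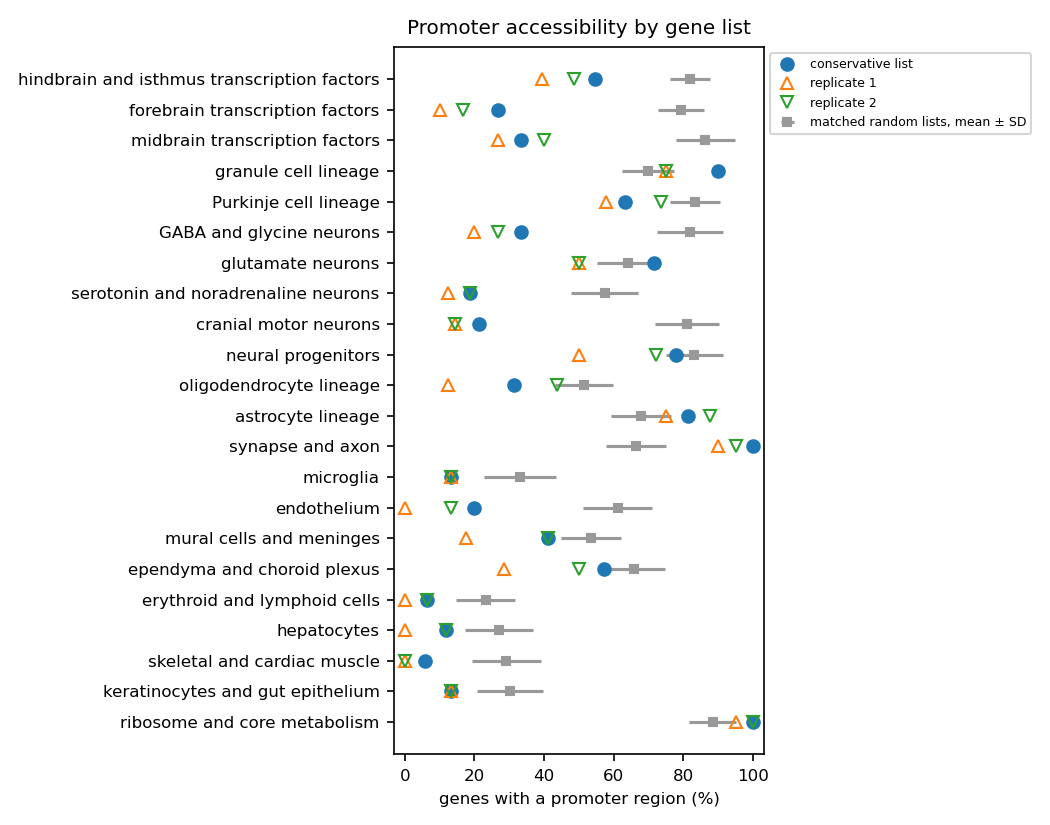
Share of genes with a promoter region (x axis, %) for each fixed gene list (y axis). Filled circles are the conservative list, open triangles the lists of replicates 1 and 2, and grey squares the mean of 10000 matched random lists with bars of 1 SD. The synapse and axon list lies above its matched lists at 100%, and the forebrain factors lie below theirs at 26.7%.

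Genes of neural progenitors and of the astrocyte, granule cell and oligodendrocyte lineages had more distal regions than matched genes. Distal regions lay over 1 kb from every protein-coding TSS and were counted within 50 kb of the most upstream TSS of a gene. A region near several genes was counted for each, and the permutations took genes as independent. Neural progenitor genes had a mean of 3.28 such regions (SD over genes 2.22, n = 18 genes), 3.03 times the matched mean. Astrocyte lineage genes had 2.94 (SD 2.41, n = 16), 2.80 times the matched mean, and granule cell lineage genes 2.40 (SD 1.76, n = 20), 2.33 times. Each of these 3 lists had a permutation adjusted p of 0.00147, from the same smallest raw p. Oligodendrocyte lineage genes had 2.25 (SD 1.69, n = 16), 2.40 times the matched mean (permutation adjusted p = 0.00440). In the lists of replicates 1 and 2 the means were 1.61 and 2.72 for progenitors, 1.81 and 2.81 for astrocytes, 1.40 and 2.15 for granule cells, and 1.06 and 2.06 for oligodendrocytes. Differences between lists were not tested. Notch1, a receptor that maintains progenitors with its TSS at chromosome 2, 26516663, had 9 distal regions, Nes 6 and Ascl1 5. Aldh1l1, a folate enzyme of astrocytes, had 8 and Id3 7. Mbp, a protein of the myelin sheath, had 5 distal regions around its most upstream TSS, at chromosome 18, 82475146. It had no promoter region in either replicate but was open in the replicated list. Nfix, a nuclear factor I gene, had 5.

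The remaining 18 lists did not pass for distal regions in the conservative list. The lowest permutation adjusted p among them was 0.0704, for hindbrain and isthmus factors, with a mean of 1.73 regions (1.56 times the matched mean). Muscle genes had 1.71 (permutation adjusted p = 0.0742), and glutamate neuron genes 1.86 (0.0869). In replicate 1 alone the oligodendrocyte call was lost (permutation adjusted p = 0.0814). Among regions above the median signal value, 1 of the 4 lists with more distal regions passed, that of astrocytes. In the replicated list hindbrain factors, GABA and glycine neurons, glutamate neurons, synapse and axon, microglia and muscle also passed. Hindbrain factors and glutamate neurons passed within 20 kb, hindbrain factors without matching, synapse and muscle genes in the optimal list, and muscle genes within 100 kb.

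**Figure D2:**
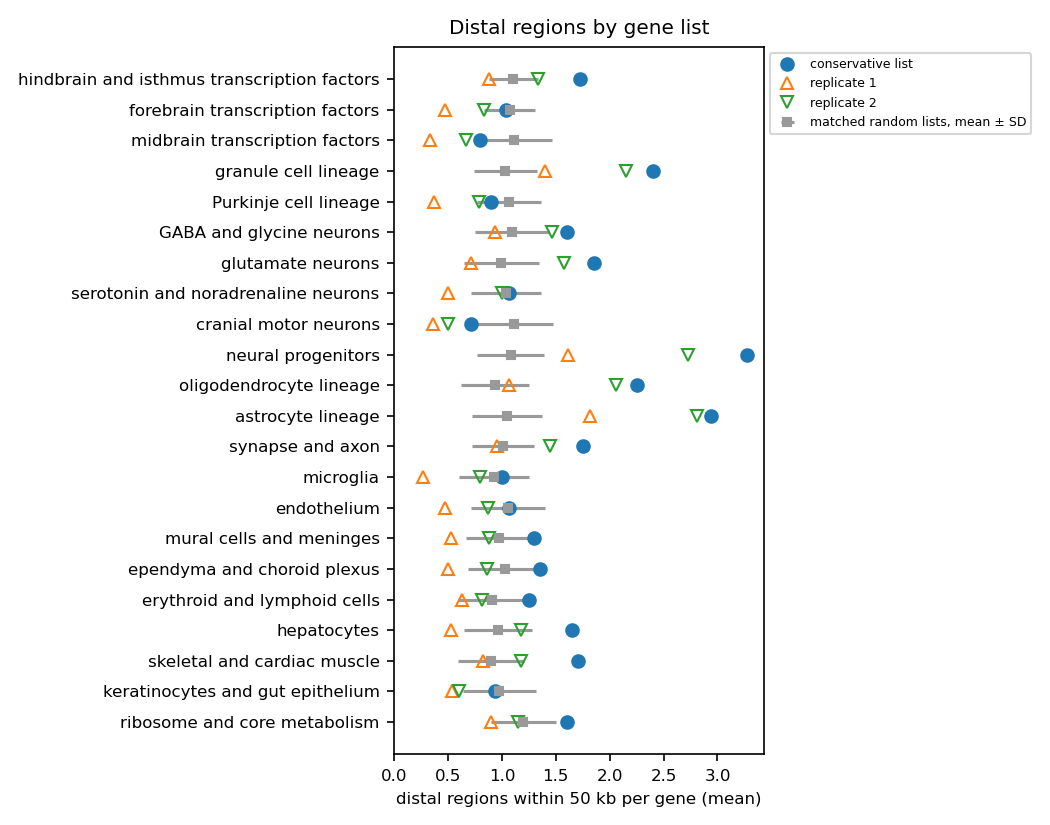
Mean number of distal regions within 50 kb per gene (x axis) for each fixed gene list (y axis). Filled circles are the conservative list, open triangles the lists of replicates 1 and 2, and grey squares the mean of 10000 matched random lists with bars of 1 SD. Neural progenitors are highest at 3.28.

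Hindbrain and forebrain factors were also compared directly. More hindbrain than forebrain factors had an open promoter, 54.5% of 33 against 26.7% of 30 (Fisher's exact test, two-sided p = 0.0398). In replicate 1 the shares were 39.4% and 10.0% (Fisher's exact p = 0.00942), and in replicate 2 they were 48.5% and 16.7% (Fisher's exact p = 0.00879). Distal regions numbered 1.73 (SD 1.46, n = 33) per hindbrain factor and 1.03 (SD 1.59, n = 30) per forebrain factor. The difference of 0.694 did not pass a two-sided permutation test (p = 0.0864). Members of a list that lie close together share regions, so their counts are not independent, and the permutation p values do not allow for this. The difference was 0.412 in replicate 1 and 0.5 in replicate 2, and 1.98 in the replicated list (permutation p = 0.00742 in the replicated list). Zic1, a factor of cerebellar granule cell precursors, had 5 distal regions, and En1 and En2, which pattern the midbrain and cerebellum, had 4 each. Among forebrain factors Nr2f1, a nuclear receptor, had 8 and Nr2f2 had 4. Bcl11b, Dlx1, Dlx2 and Dlx5 had no promoter region in the list of either replicate, and Bcl11b was open in the conservative list.

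Of 39 Hox genes, which set position along the body axis, 3 had a promoter region. All belonged to paralog groups 1 to 5: Hoxa1, Hoxa5 and Hoxc5, or 3 of 15 genes. None of 16 genes of groups 9 to 13 and none of 8 genes of groups 6 to 8 had one. The difference between groups 1 to 5 and 9 to 13 did not pass Fisher's exact test (two-sided p = 0.101). In the replicated list 12 of 15 and 6 of 16 were open (Fisher's exact p = 0.0290). The Hoxa1 region lay at chromosome 6, 52157847 to 52159448, over the TSS of the gene at 52158317, with signal values of 5.98 in replicate 1 and 4.94 in replicate 2. The Hoxa5 region lay at chromosome 6, 52204332 to 52204784, and the Hoxc5 region at chromosome 15, 103014018 to 103014542, and neither was in the list of a single replicate. Hoxa4 and Hoxa7 had a promoter region in replicate 2.

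**Figure D3:**
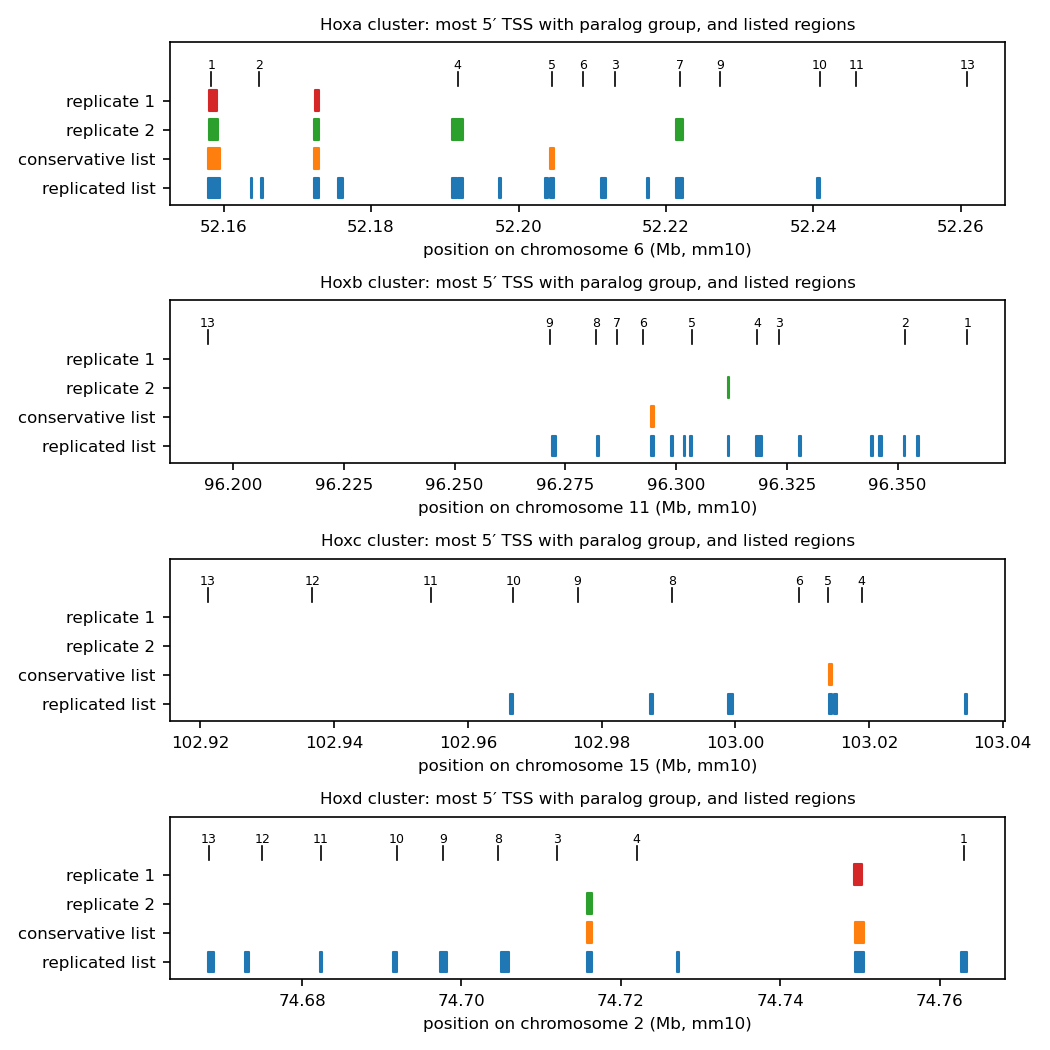
Listed regions (bars) in the Hoxa, Hoxb, Hoxc and Hoxd clusters by position on the chromosome (x axis, Mb, mm10), with 1 row for each peak list. Ticks mark the most upstream TSS of each gene with its paralog group. The conservative list holds 3 regions in Hoxa, 1 in Hoxb, 1 in Hoxc and 2 in Hoxd.

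Of 25 fixed motifs, 17 were more frequent within 100 bp of distal summits than in windows of matched GC and CpG content, and 1 was less frequent (Fisher's exact test over windows, adjusted over the motifs). CTCF, which anchors chromatin loops, had a site in 7.40% of 18327 windows against 0.0917%, a ratio of 80.8 (exact 95% interval 64.8 to 102). The X-box of RFX factors occurred in 110 distal windows and in 1 of 91635 matched windows, so its ratio of 550 has a wide interval, 96.7 to 21919. In the replicated list, with 12 matched windows, the RFX ratio was 94.2 (52.9 to 185), and within 50 bp of summits, with 2, it was 192.5 (51.5 to 1618). The full site of nuclear factor I was 7.08 times as frequent (3.19 to 16.3), but 3.40 times against shuffled windows (1.20 to 11.8) and 21.7 times within 50 bp (5.95 to 119), and the CAGATG type of E-box, bound by proneural factors, 4.16 times (3.66 to 4.74). MEF2 sites gave 2.77, MEIS-PBX sites 2.74, homeodomain sites 2.56, the POU octamer 2.53, NRF1 sites 2.35, the CAGCTG type of E-box 2.31 and SOX sites 2.23. ROR sites gave 1.99, the NFY CCAAT box 1.88, the GC box 1.67, ZIC sites 1.53 and TEAD sites 1.25. Against shuffled windows the ratio was 8.29 for the GC box, 6.40 for NRF1, 4.73 for homeodomain and 3.83 for POU sites. Within 50 bp it was 127 for CTCF, 5.16 for MEF2, 3.90 for homeodomain and 3.94 for POU sites. In replicates 1 and 2 the ratio of the CAGATG E-box was 5.10 and 3.60, that of CTCF 57.9 and 78.4, that of RFX 320 and 345, again from 1 matched window each (intervals 55.4 to 12834 and 59.9 to 13822), and that of nuclear factor I 12 and 7.22. GATA sites were less frequent, at 0.528 of the matched share (0.431 to 0.641). The HOX-PBX site had a ratio of 1.08 (0.720 to 1.57), and those of HNF4, HNF1, SPI1 and REST also did not pass. SPI1 matched 13 distal windows. HNF1 and REST matched 1 each, with intervals of 0.0317 to 20.8 and 0.0181 to 6.87, too few to judge. EBF sites did not pass (0.920) but were less frequent in replicate 1 (0.641, Fisher's exact adjusted p = 0.00828). ETS sites did not pass (1.51, Fisher's exact adjusted p = 0.129) but were more frequent in replicate 1 (3.18), replicate 2 (2.26), above the median signal value (3.48) and against shuffled windows (4.43). They did not pass in the replicated list (1.15, Fisher's exact adjusted p = 0.414) or within 50 bp (1.89, 0.0749). AP-1 sites were 1.3 times as frequent against matched windows and did not pass against shuffled windows (Fisher's exact adjusted p = 0.837), nor did ZIC sites (0.342). TEAD sites did not pass above the median signal value.

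**Figure D4:**
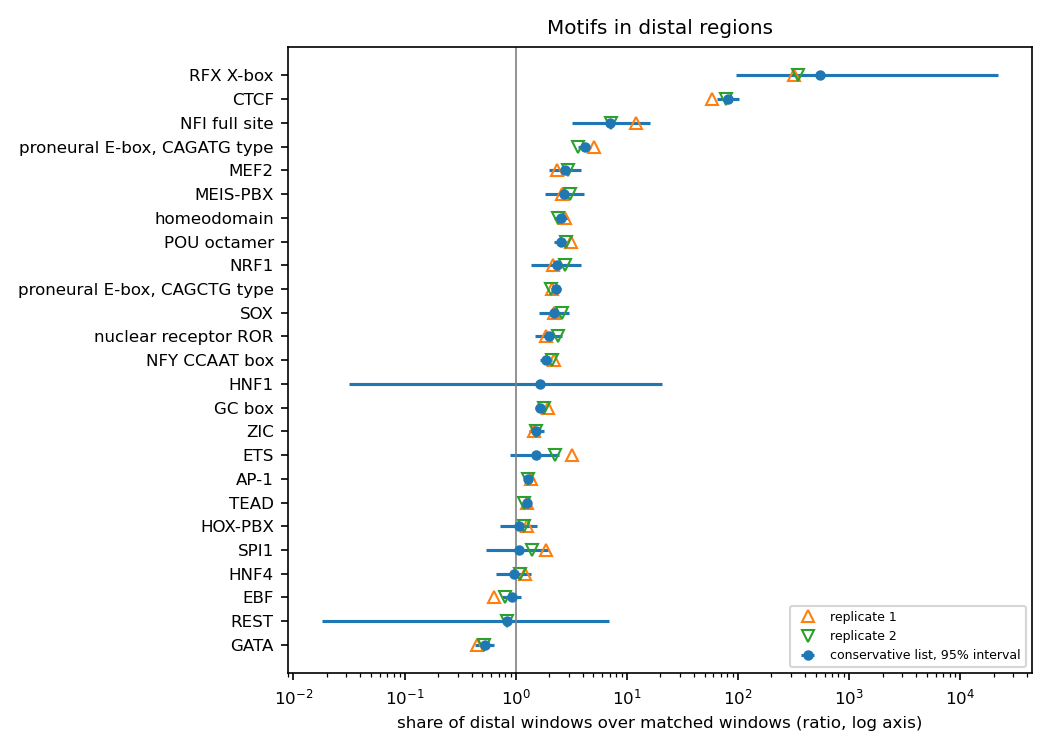
Share of distal windows with a motif over that of matched windows (x axis, ratio on a log scale) for 25 motifs (y axis). Filled circles are the conservative list with exact 95% intervals, and open triangles the lists of replicates 1 and 2. RFX and CTCF lie farthest above 1, at 550 and 80.8, and of the motifs that passed GATA lies lowest at 0.528.

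Outside the lists, the genes with the most distal regions were Fcgr3 with 13, Thra, a thyroid hormone receptor, with 12, and Hfe2 with 11. In replicates 1 and 2 they had 7 and 9, 5 and 9, and 4 and 8. The order differed there, since Btn1a1, with 10, had 7 and 9. Some of the genes with the most distal regions are neighbours whose windows overlap, so their counts can share regions. They are Btn1a1, Abt1 and Btn2a2 on chromosome 13, and Hfe2 and BC107364 on chromosome 3. Whether the regions act on these genes was not tested. Only protein-coding TSS were excluded, so distal regions can lie at the TSS of other gene types. With the TSS of all gene types the promoter share was 46.0%, against 39.6%. The distal region with the highest signal value, 54.4, lay at chromosome 2, 69355469 to 69355735, in intergenic sequence 12985 bp from the TSS of Abcb11. The next, 53.7, lay at chromosome X, 143482936 to 143483180, 35531 bp from Pak3. All 10 strongest distal regions were intergenic. Of these, 5 aligned to mitochondrial DNA and 7 had another copy on the chromosomes, and these sets overlap, so that 9 had either kind of copy. Over the 11305 genes open in both lists, promoter signal had a Spearman correlation of 0.939 across genes.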

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

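The tests of promoters of like signal, of regions in replicate 1 alone, of copies on chromosomes and of each regional list were chosen after the result was seen. Peaks past the score threshold in the ranked lists were missing from the thresholded lists: 276 for both replicates, 189 for replicate 1 and 220 for replicate 2. Of these, 93, 46 and 65 lay outside the numbered chromosomes, X and Y, where the thresholded lists hold no peaks. The other 183, 143 and 155 lay on those chromosomes. Mitochondrial and unplaced sequence were not counted apart. The highest signal values of the missing peaks were 45.4, 42.5 and 44.2. The deposited file descriptions name a further source file for the thresholded lists, and whether it removes these peaks was not settled. They lie outside the lists that the comparisons used and need not mark missed accessible regions.

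Replicate 2 listed more regions than replicate 1, and of 7656 regions in replicate 2 alone, 90.7% overlapped the less strict ranked list of replicate 1, against 2.78% at random, and their median signal percentile was 21.5. The 1792 regions in replicate 1 alone gave 95.7% and 20.7, with no random level computed. Lists of different lengths are not comparable in these values, so they cannot point to either replicate. In the ranked list that pairs the replicates, 1 replicate had the higher −log10 p in 70.3% of peaks, but the list does not name it. Of the values in its 2 columns, 99.2% and 98.6% occur in the ranked lists of the single replicates. They were looked up in both lists together and were not traced to either replicate. Deeper or stronger signal in replicate 2 therefore stays open. The share of open promoters found in replicate 2 alone was 9.07% for all genes, 5 of 7 for oligodendrocytes, 4 of 7 for mural cells, 5 of 14 for progenitors and 2 of 2 for endothelium and for hepatocytes. An exact binomial test over genes marked these 5 of 17 cell type lists, and a permutation among promoters of like signal marked 0 of 17. Genes are not replicates and each pool is 1 library, so neither test decides, and a different mix of cell types stays open.

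Of the 10 strongest distal regions, 9 had another copy of at least 95% identity on the chromosomes or the mitochondrial genome, against 4 of 100 random distal regions. These 9 include all 5 that aligned to the mitochondrial genome, against 0 of 100 at random. Copies on the chromosomes were found for 7 of the 10, against 4 of 100. Reads from mitochondrial DNA and from other copies are a candidate source of their signal. With 1 group, no biological explanation was tested.

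Promoters of the 78 regional transcription factors were open in 39.7%, against 81.6% in matched lists. In the less strict replicated list the difference shrank to -6.01 percentage points (permutation p = 0.0820), but the lists went apart: forebrain factors were still lower there, at -17.6 points (permutation adjusted p = 0.0323), midbrain factors had -6.71 and hindbrain factors 4.76. Without matching on CpG content the difference was -18.7 points together (permutation p = 0.00160), -31.6 for forebrain factors (adjusted p = 0.00495), -24.9 for midbrain and -3.84 for hindbrain factors. Because the lists went apart, the values over all 78 factors decide neither explanation. For forebrain factors the difference without matching argues against the matching as the whole cause. The replicated list has a threshold too, so the difference left there cannot exclude a threshold as the whole cause, which stays open. Without matching the reference share falls from 81.6% to 58.4%, so a difference below matched lists shrinks whatever its cause. In the replicated list matched lists reach 89.3%, a share near its ceiling. A smaller difference in these settings therefore does not identify a cause, and both explanations stay open for hindbrain and midbrain factors. The share of cells in which each factor is active was not tested.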

How the results depend on the processing

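All settings here were planned. Read depth is unknown and limits every count of regions. Over single gene lists and motifs, 127 of 176 promoter values, 140 of 176 distal values and 127 of 150 motif values kept their direction and their side of the threshold. With or without a change of sign, 25 promoter values lost and 14 gained a call, as did 4 and 12 distal values and 3 and 6 motif values. The cause of the changes below was not tested. No paired analysis was possible because there was 1 group.

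The less strict pseudoreplicated lists held 54049 regions in replicate 1 and 66479 in replicate 2, a ratio of peaks of 1.24, and regions above the median signal numbered 10111 and 13033. The share of the regions of replicate 1 found in replicate 2 was 90.7% with 50% of the region required, 88.6% with reciprocal 50%, 89.5% with summits within 100 bp, 85.3% in the pseudoreplicated lists and 98.9% above the median signal. For the regions of replicate 2 the shares were 69.4%, 68.7%, 69.4%, 68.4% and 94.6%. The promoter share was 46.0% with the TSS of all gene types, 20.7% in the replicated list, 59.0% above the median signal and 46.8% to 53.8% without a replicate.

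Promoter lists above matched lists numbered 1 with the most upstream TSS, 0 above the median signal and 1 without either replicate. Lists below numbered 1 in the replicated list, 6 in the optimal list and 8 to 14 without a replicate. Distal lists above numbered 10 in the replicated list and 1 above the median signal. Hindbrain factors had 1.98 more distal regions than forebrain factors in the replicated list (permutation p = 0.00742). The Hox difference was 40.0 percentage points in the optimal list (Fisher's exact p = 0.00680) and 42.5 in the replicated list (0.0290). Motifs below matched windows numbered 1 to 2 without a replicate.

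Some differences from matched lists changed sign. For promoters, in percentage points, the replicated list gave 4.76 for hindbrain factors, 2.93 for GABA and glycine neurons, 3.64 for progenitors, 16.7 for oligodendrocytes, 3.24 for mural cells and 12.9 for ependyma. The optimal list gave 4.28 for progenitors and 3.5 for oligodendrocytes, and no matching 4.84 for Purkinje cells and 19.4 for progenitors. Above the median signal granule cells had -5.86 and glutamate neurons -15.5, and glutamate neurons -12.5 to -7.13 without a replicate. None of these passed the threshold in the new direction.

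For distal regions per gene, forebrain factors had 0.169 within 20 kb, 0.0122 without matching, 0.0934 in the optimal list, 0.630 in the replicated list and -0.0361 to 0.0359 without a replicate. The replicated list gave 0.336 for Purkinje cells and -0.346 for endothelium, which had -0.0202 in the optimal list and -0.0472 to 0.0544 without a replicate. Within 20 kb cranial motor neurons had 0.00495 and keratinocytes 0.106. Above the median signal the differences were -0.0818 for serotonin neurons, 0.0129 for cranial motor neurons, -0.0365 for microglia, -0.0212 for mural cells, -0.182 for ependyma and 0.0197 for keratinocytes. Microglia had -0.0197 without matching and -0.197 to 0.0763 without a replicate, and keratinocytes -0.158 to 0.0515. None of these passed the threshold.

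For motifs, in percentage points of windows, shuffled windows gave -0.0729 for AP-1, 0.0625 for EBF and 0.00521 for REST. Within 50 bp the differences were -0.0366 for HOX-PBX, 0.0151 for HNF4, -0.00215 for HNF1 and 0.00538 for REST. The replicated list gave -0.0168 for SPI1, 0.0326 for EBF and 0.00997 for REST. REST passed the threshold there (Fisher's exact adjusted p = 0.0104), on 8 of 58196 distal windows. Above the median signal HNF4 had 0.0642 and HNF1 -0.00642. Without a replicate HNF4 had 0.0199 to 0.0499 and HNF1 -0.00454 to -0.00306.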
